A study of Homo sapiens with 6 samples.

How the data were processed

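Polyadenylated RNA of MDA-MB-231 cells was measured in 6 libraries, 3 with scrambled shRNA and 3 labelled SCUBE3 knockdown. Per the labels' protocols, libraries were made with a stranded mRNA kit and sequenced as single reads of 50 bases, on an Illumina HiSeq 3000 per the series' design text. Per the submitters' processing notes, bcl2fastq, TopHat2 2.0.8b and HTSeq were used with the genome build hg19. HTSeq's strand setting and overlap mode and the annotation release are not given in the sources used here, so reads of overlapping or antisense genes may not be told apart. The deposited values are raw read counts per gene symbol, 1 file per library, without normalization by the authors. Each file lists 23228 genes, of which 5725 had 0 reads in every library, and 5 summary lines for reads given to no gene, which were left out of library sizes and tests.

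Those summary lines differed between the groups. Reads aligned to several places made up 34.1% ± 0.106 (SD, n = 3) of the total in scramble files and 29.4% ± 0.175 in files labelled knockdown. Reads in no annotated gene made up 14.7% ± 0.275 and 11.1% ± 0.0540, and reads in more than 1 gene 0.537% ± 0.00504 and 0.593% ± 0.00441. Each of these differences had an exact permutation p of 0.1 with n = 3 per group, the smallest this design allows. Genes with at least 1 read numbered 15349 ± 22.7 in scramble and 15832 ± 55.2 in the other group. Library totals in genes ran from 21348509 to 25520901 reads. Reads carry no molecular identifiers, so the floors and the counting intervals of ratios cover counting error only.

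Samples were grouped by their titles. Genes kept by edgeR's filterByExpr (13606) were scaled by TMM and tested with the quasi-likelihood F test (edgeR 4.0.16, R 4.3.3; robust, two-sided, group as the single term), with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors are the fold change divided by the root of F. CPM are scaled by the TMM factors. A gene with 0 reads in a group is given as a lower bound against a floor of 3 reads over that group, and one with 1 to 3 reads as a ratio with an exact 95% counting interval. The common dispersion was 0.00103, a biological coefficient of variation of 3.21%. Libraries of 1 group differed by more than sampling noise (chi-square per degree of freedom 1.68 to 3.47), so none were merged as copies of 1 library; this does not show that they came from separate cultures.

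Before the data were examined, 44 gene lists, the comparison, the alternatives and the rule for naming genes were fixed. Lists with at least 3 tested members were tested with camera (limma 3.58.1, preset inter-gene correlation 0.01, two-sided, Benjamini-Hochberg over the lists). The SCUBE family had 1 tested member, and the list of mitochondrially encoded genes matched no symbol in the files, so neither was tested. A symbol missing from the files was looked up among RefSeq synonyms, which matched 3 more. Named genes are the SCUBE family, the 10 largest positive and 10 largest negative changes among genes past the threshold with at least 5 CPM in the higher group and no overlap between groups, up to 4 members per list by adjusted p, and the 5 smallest adjusted p-values. Some of the genes chosen are not reported here. Identifiers without a gene name were left out of the largest changes and of the 5 smallest. A further 29 genes, among them CD74, HLA-DRA, HLA-DPA1, B2M, CDH1, VIM, ZEB1, SNAI2, CD274, RPS18, RPS19, RPLP0 and those named among the other observations, were chosen after their values were seen. CDKN2A, CDKN2B and MTAP were chosen after the largest changes had been seen but before their own values, and AXL, EGFR, CD44, GATA3 and ERBB3 were added as genes reported as high or low in MDA-MB-231.

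Alternatives were DESeq2's size factors, upper-quartile scaling and library totals, no low-count filter and a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, each library left out, a threshold of 0.01, a test against a 1.5-fold change, camera with an estimated correlation, and fry. Added after seeing the data were a correction for GC content and transcript length (a loess curve per library over 12999 genes, 95.5% of those tested, with 1 GENCODE transcript per gene) and windows of 100 neighbouring genes. The rule for choosing that transcript was changed after a first count of genes under the correction and first values of uniqueness of ribosomal protein transcripts had been seen. Gene order came from RefSeq's annotation of GRCh38.p14, which held 13093 of the genes (96.2%) and was used for names and neighbours only, since the counts were made on hg19.

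The fit was tested on simulated counts for the 13606 genes of this comparison, with 50 genes changed at each of 4 sizes. It recovered 64% of genes changed 1.2-fold, 78% at 1.5-fold, 96% at 2-fold and 96% at 4-fold, and 4.02% of its calls were false. In a simulated raise of the NF-kB list, camera called that list and 0 of 39 lists without its genes. The first simulation changed 200 genes in all and the second only the genes of that list, whereas 11681 genes passed the threshold in the data. Neither can therefore show how many of the gene or list calls made here are false. When the libraries were split so that each side mixed both groups, 6 to 14 lists passed although 0 genes did. Each such split is uneven and keeps part of the group difference in its comparison, so these counts are not a rate of false calls.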

Results

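The data are 6 RNA-seq libraries of MDA-MB-231, an established human breast cancer cell line of the triple-negative, mesenchymal-like kind. According to the labels, the cells received lentivirus with either a scrambled short hairpin RNA (shRNA) or an shRNA against SCUBE3 and were then kept under puromycin. SCUBE3 encodes a secreted and cell-surface protein with EGF-like domains and a CUB domain. The series' title places the work in a study of SCUBE3 in oncogenic signalling and anti-tumour immunity, and the comparison asks which transcripts differ between cells with the 2 kinds of shRNA. There were 3 libraries per group. Reads assigned to genes numbered 24234762, 21348509 and 22571333 in scramble replicates 1 to 3, and 24495995, 25520901 and 24249429 in the libraries labelled knockdown. The labels call the libraries replicates but do not say that they came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

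SCUBE3 RNA was not lower in the libraries labelled knockdown. SCUBE3 had 96, 91 and 80 reads in the scramble libraries and 99, 107 and 101 reads in the libraries labelled knockdown, or 3.995 ± 0.373 against 4.06 ± 0.0837 CPM (read counts scaled by library size and TMM factor; SD, n = 3). The log2 fold change was 0.03 with a standard error (SE) of 0.14 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.871), and an exact two-sided permutation test on CPM gave p = 0.8 with n = 3 per group, where 0.1 is the smallest value possible. The 95% interval of the log2 fold change ran from -0.26 to 0.31, so the largest drop in SCUBE3 RNA within it was 16.6%. Without scramble replicate 3 the estimate was -0.05. Because the targeted transcript was not lower, the groups are called scramble and "labelled knockdown" throughout, and each direction given here is that of the labels. The labels' protocol says that SCUBE3 was examined by western blot, and protein was not analysed here. Of its relatives, SCUBE2 had 9, 2 and 2 reads against 6, 7 and 7 (exact permutation p = 0.4, n = 3 per group). SCUBE1 had 0 reads in all 6 libraries, which allows up to 0.0448 CPM in scramble and 0.0397 CPM in the other group (3 reads over the group, counting error only).

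**Figure D1:**
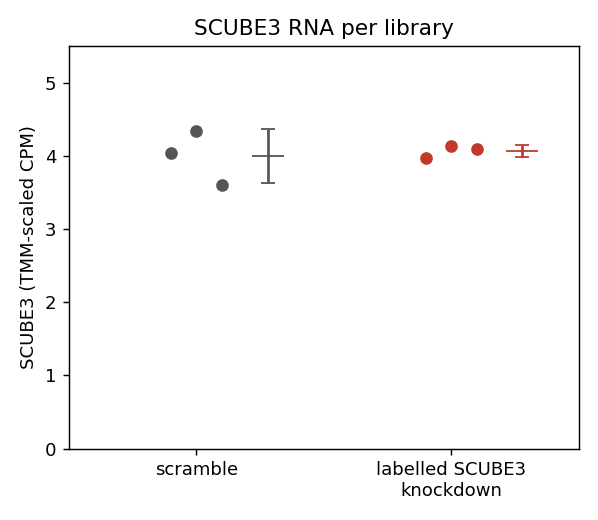
SCUBE3 in each library, in TMM-scaled CPM (vertical axis), for the 3 scramble libraries and the 3 libraries labelled knockdown (points), with the mean and SD beside them. The groups overlap, at 3.995 ± 0.373 and 4.06 ± 0.0837 CPM.

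The rest of the transcriptome differed widely between the groups, and many genes were read in 1 group only. LCN2, a secreted siderophore-binding protein, had 0 reads in scramble and 26.2 ± 1.36 CPM (SD, n = 3) in the libraries labelled knockdown, which makes it at least 586-fold higher there. FGF13, an intracellular member of the fibroblast growth factor family, had 27.1 ± 1.48 CPM in scramble and 0 reads in the other group, at least 684-fold lower with the knockdown label. LCP1, the actin-bundling protein L-plastin, had the smallest adjusted p of all genes: 666 ± 19.3 CPM in scramble against 2.70 ± 0.234, a log2 fold change of -7.94 ± 0.06 (SE; edgeR quasi-likelihood adjusted p = 2.67e-49). S100A4, a calcium-binding protein linked to cell motility, went the other way, from 2.58 ± 0.680 to 563 ± 7.41 CPM (log2 fold change 7.78 ± 0.06).

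Of 13606 genes tested, 11681 (85.9%) passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 5899 higher and 5782 lower in the libraries labelled knockdown. A log2 fold change of at least 1 in size was reached by 4247 of them, 2376 higher and 1871 lower, and one of at least 3 by 901. The 3 libraries of each group did not overlap for 11676 genes (85.8%), where chance gives 10%. With a test against a 1.5-fold change in place of 0 (edgeR glmTreat), 6251 genes passed. In all, 53 genes had 0 reads in scramble and a mean of at least 1 CPM in the other group, and 30 genes the reverse. Replicates lay close together: Pearson's r of log2(CPM + 1) across genes was 0.998 to 0.999 within groups and 0.891 to 0.896 between them. Genes are not independent replicates.

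The 10 largest positive changes among genes with at least 5 CPM in the higher group belonged to LCN2 and 9 others. SELENBP1 was at least 277-fold higher in the libraries labelled knockdown, ZNF542 at least 239-fold, RHBDL2 at least 170-fold, ARSI at least 132-fold, MAP1LC3A at least 127-fold and SPINK4 at least 113-fold, each with 0 reads in scramble. FAM83A had 1 read in scramble and 1604 in the other group, a ratio of 1420 (95% counting interval 255 to 56134). CX3CL1, the membrane-bound chemokine fractalkine, had 1 and 1017 reads (ratio 901, 161 to 35604), and HLA-DRB1, an MHC class II chain, had 3 and 3152 (ratio 930, 318 to 4514).

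The 10 largest negative changes were those of FGF13 and 9 others. AUTS2 was at least 604-fold lower in the libraries labelled knockdown, FAM84A at least 435-fold, DENND1C at least 335-fold, HTR1F at least 210-fold, RIMBP2 at least 208-fold, NCKAP1L at least 160-fold and ZDHHC15 at least 132-fold. FOXR2, a forkhead factor, had 2365 reads in scramble and 1 in the other group (ratio 2671, 95% counting interval 479 to 105537), and HS6ST2, a heparan sulfate sulfotransferase, had 2079 and 1 (ratio 2348, 421 to 92779). Besides LCP1 and S100A4, the smallest adjusted p-values belonged to the adhesion receptor GPR116 (log2 fold change 7.66 ± 0.06), the macrophage growth factor CSF1 (4.71 ± 0.04) and the plasminogen activator PLAT (4.40 ± 0.04).

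**Figure D2:**
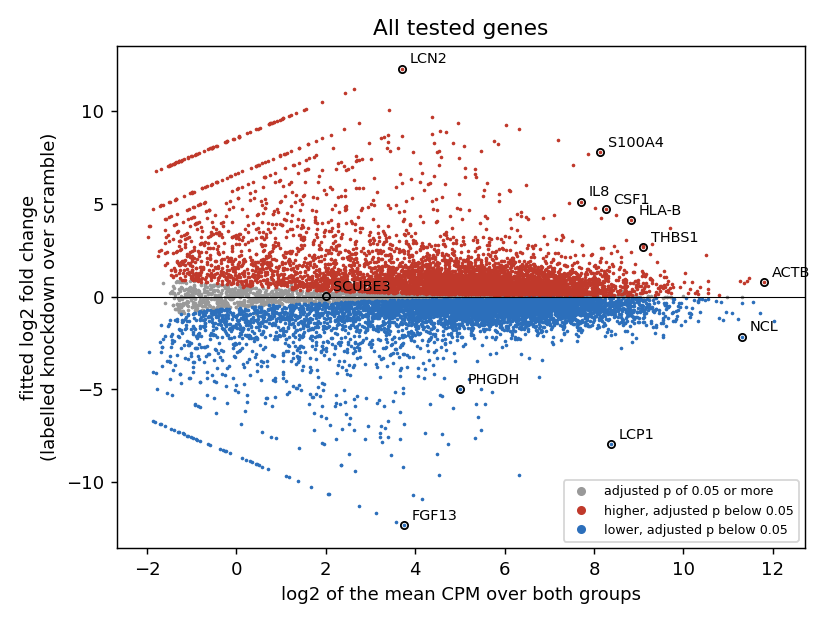
Fitted log2 fold change, labelled knockdown over scramble (vertical axis), against the log2 of the mean CPM over both groups (horizontal axis) for the 13606 tested genes, coloured by direction where the adjusted p is below 0.05. SCUBE3 sits at 0.03 among genes changed by far more, such as LCP1 at -7.94 and S100A4 at 7.78, and genes with 0 reads in 1 group form the outermost slanted lines, where fitted values are not bounds.

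Antigen presentation genes were higher in the libraries labelled knockdown almost without exception. Of 29 tested, 28 were higher, 0 were lower and TAPBPL did not pass, with a median log2 fold change of 1.81. HLA-B rose from 49.4 ± 1.91 to 865 ± 24.3 CPM (SD, n = 3), a log2 fold change of 4.13 ± 0.04 (SE). HLA-C (2.78 ± 0.04) and the peptide-loading chaperone TAPBP (2.81 ± 0.04) were higher too. MHC class II genes, read at trace level in scramble, were clearly read in the other group: HLA-DRA had 0.219 ± 0.241 against 131 ± 3.36 CPM and HLA-DPA1 0.0909 ± 0.0466 against 62.1 ± 0.652, while the invariant chain CD74 went from 28.5 ± 3.77 to 542 ± 13.8. B2M, the light chain of class I molecules, changed less (0.56 ± 0.03). HLA genes resemble one another, so the split of their reads is uncertain. The list passed limma's camera test with a preset correlation (adjusted p = 9.77e-27) but not with an estimated correlation (adjusted p = 0.0692).

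Chemokines and cytokines had the highest list median, 3.96, with 26 of 30 tested members higher and 3 lower. IL6 rose from 0.562 ± 0.214 to 69.1 ± 1.47 CPM (SD, n = 3), and IL8, a neutrophil chemoattractant, from 11.7 ± 1.68 to 408 ± 14.1. CSF2 (log2 fold change 5.16 ± 0.08) and CSF1 were higher as well. NF-kB target genes were higher in 23 of 26 cases and lower in 3, with a median of 1.63. The adhesion molecule ICAM1 (5.07 ± 0.05), the signalling adaptor TRAF1 (3.66 ± 0.07), TNFAIP2 (1.83 ± 0.04) and the early-response gene IER3 (2.74 ± 0.03) had the smallest adjusted p-values in that list. Both lists passed limma's camera test (adjusted p = 8.90e-14 for chemokines and 4.27e-14 for NF-kB targets), and both held with an estimated correlation (adjusted p = 0.0305 for each).

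Type I interferon response genes were mostly but not uniformly higher, 28 of 44 higher and 11 lower, with a median of 0.91. IFI27 had 0.0908 ± 0.0494 CPM in scramble and 47.1 ± 2.13 in the libraries labelled knockdown, and BST2, which tethers budding virus, had 2.48 ± 0.649 and 134 ± 5.11 (SD, n = 3). ISG15 (log2 fold change 2.39 ± 0.06) and IFIT3 (1.46 ± 0.04) were higher. Immune checkpoint and NK ligands were higher in 17 of 19 cases and lower in 2, with a median of 1.40. The list's members HLA-E (1.73 ± 0.03), MICA (1.69 ± 0.05), LGALS1 (2.73 ± 0.04) and LGALS3 (1.43 ± 0.04) were higher, and CD274, which encodes PD-L1, by less (0.32 ± 0.05). Both lists passed limma's camera test with the preset correlation (adjusted p = 1.80e-04 and 1.01e-04) and neither with an estimated correlation (adjusted p = 0.0692 for each).

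Matrix proteases and inhibitors were higher in 19 of 26 cases and lower in 5, with a median of 1.26. PLAT went from 32.5 ± 1.12 to 685 ± 19.1 CPM and the lysosomal protease CTSD from 118 ± 7.94 to 1534 ± 18.8 (SD, n = 3). The urokinase gene PLAU was higher (log2 fold change 2.45 ± 0.03). Angiogenesis factors were higher in 15 of 19 cases and lower in 3, with a median of 0.82. They included VEGFA (2.27 ± 0.04) and CXCL1 (4.28 ± 0.06), and also THBS1 (2.68 ± 0.03), which is known as an inhibitor of angiogenesis. Both lists passed limma's camera test (adjusted p = 2.46e-12 and 7.65e-07), also with an estimated correlation (adjusted p = 0.0305 and 0.0466).

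Collagens and matrix genes were higher in 21 of 29 cases and lower in 6, with a median of 0.88. COL6A3 rose from 0.466 ± 0.193 to 42.3 ± 2.51 CPM (SD, n = 3), and COL5A1 had a log2 fold change of 3.10 ± 0.04. Integrins and focal adhesion genes were higher in 17 of 25 cases and lower in 5, with a median of 0.55. ITGB5 (1.89 ± 0.04), ITGA3 (1.26 ± 0.03) and CAV1 (1.10 ± 0.03) were higher, and the actin-linked adhesion protein TNS1 was lower (-5.76 ± 0.08). Both lists passed limma's camera test with the preset correlation (adjusted p = 7.65e-07 and 0.00714) and neither with an estimated correlation (adjusted p = 0.0692 and 0.342).

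Epithelial genes and some mesenchymal genes were higher in the same libraries. Of 18 epithelial markers tested, 15 were higher and 2 lower, with a median of 2.04. The tight-junction gene CLDN4 (log2 fold change 4.19 ± 0.06), the keratin genes KRT7 (3.31 ± 0.04) and KRT19 (0.94 ± 0.04), and CLDN7 (2.02 ± 0.08) were higher, and CDH1, which encodes E-cadherin, had 3 reads in scramble and 152 in the other group. Mesenchymal markers were higher in 11 of 19 cases and lower in 7, with a median of 0.88. TGFBI (2.22 ± 0.05), COL6A2 (2.80 ± 0.06) and the zinc-finger factor SNAI2 (1.11 ± 0.06) were higher, while VIM (-0.87 ± 0.03) and ZEB1 (-0.94 ± 0.04), an E-cadherin repressor, were lower. Both lists passed limma's camera test with the preset correlation (adjusted p = 1.19e-05 and 4.23e-04) and neither with an estimated correlation (adjusted p = 0.118 and 0.130). Without a low-count filter the mesenchymal list lost its call (camera adjusted p = 0.112), and with limma-voom too (0.159).

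TGF-beta response genes were higher in 21 of 30 cases and lower in 7, with a median of 0.52 (limma camera adjusted p = 4.08e-05; adjusted p = 0.121 with an estimated correlation). TIMP3, a metalloprotease inhibitor, went from 154 ± 11.4 to 1107 ± 23.4 CPM (SD, n = 3), whereas CTGF was lower (log2 fold change -1.44 ± 0.03). Among TGF-beta ligands and receptors, 7 of 13 were higher and 2 lower, with a median of 0.24 (camera adjusted p = 0.0868). TGFB2 (2.06 ± 0.04), TGFBR1 (1.76 ± 0.04) and the convertase FURIN (1.57 ± 0.05) were higher and TGFB1 (-1.15 ± 0.04) lower. BMP response genes leaned the other way, 9 of 11 lower and 2 higher, with a median of -1.75, though the list did not pass (camera adjusted p = 0.0792). ID1 (-1.35 ± 0.06), ID3 (-2.79 ± 0.09), ID4 (-3.15 ± 0.18) and MSX2 (-2.26 ± 0.14) were lower. Without a low-count filter the BMP list passed (camera adjusted p = 0.0435).

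Receptor tyrosine kinases and ligands were higher in 16 of 25 cases and lower in 7, with a median of 0.62 (limma camera adjusted p = 0.0140; adjusted p = 0.130 with an estimated correlation). DDR1, a collagen receptor (log2 fold change 2.41 ± 0.06), TGFA (1.91 ± 0.05), EPHB4 (1.95 ± 0.05) and FGFR1 (1.38 ± 0.04) were higher. Other pathway lists did not pass camera and moved both ways. ERK feedback genes were higher in 8 and lower in 8 of 22 cases (median -0.05, adjusted p = 0.233), with DUSP4 higher (0.92 ± 0.03) and FOSL1 lower (-1.07 ± 0.03). YAP/TEAD targets were higher in 9 and lower in 13 of 24 (median -0.09, adjusted p = 0.880), with WWC1 (1.34 ± 0.04) and the tissue factor gene F3 (1.19 ± 0.03) higher and CTGF (-1.44 ± 0.03) lower. Wnt targets were higher in 5 and lower in 5 of 12 (median -0.14, adjusted p = 0.214), with the Wnt antagonist DKK1 (1.78 ± 0.03), RNF43 (4.96 ± 0.22) and MYC (1.51 ± 0.04) higher. Notch genes were higher in 7 and lower in 6 of 13 (median 0.42, adjusted p = 0.354), with the ligand genes JAG1 (0.95 ± 0.04) and JAG2 (4.65 ± 0.20), LFNG (1.81 ± 0.10) and NOTCH2 (0.52 ± 0.03) higher. Hedgehog genes were higher in 6 and lower in 5 of 12 (median 0.33, adjusted p = 0.798), with CDON (1.06 ± 0.06) higher and GLI2 (-1.40 ± 0.09), GLI3 (-1.10 ± 0.06) and BCL2 (-1.60 ± 0.06) lower. Stemness genes were higher in 4 and lower in 6 of 11 (median -0.16, adjusted p = 0.697), with CD44 (0.86 ± 0.03) and ALDH1A3 (4.85 ± 0.17) higher and EZH2 (-0.99 ± 0.04) lower. Against their medians, the ERK, YAP/TEAD and stemness lists had positive means (0.15, 0.13 and 0.44) and a camera direction of higher. The Wnt list had a mean of -0.13 and a camera direction of higher, and the Hedgehog list a mean of -0.26 and a camera direction of lower.

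Replication genes were more often lower than higher in the libraries labelled knockdown. In the S phase and replication list 27 of 42 were lower and 9 higher, with a median of -0.32 (limma camera adjusted p = 0.0326; adjusted p = 0.238 with an estimated correlation). POLA1, the catalytic subunit of DNA polymerase alpha, had a log2 fold change of -1.28 ± 0.04, the ribonucleotide reductase gene RRM2 -0.85 ± 0.03, the clamp loader gene RFC3 -1.06 ± 0.04 and the flap endonuclease gene FEN1 -0.75 ± 0.03. Mitosis genes were lower in 23 and higher in 11 of 42 cases, with a median of -0.15 (camera adjusted p = 0.314). The proliferation marker MKI67 (-0.85 ± 0.03) and HMMR (-1.56 ± 0.06) were lower, and CCNA2 (1.08 ± 0.04) and KIF2C (0.89 ± 0.04) higher. Among p53 targets, 13 of 27 were higher and 12 lower (median 0.04, camera adjusted p = 0.232), with the cell-cycle inhibitor CDKN1A (1.91 ± 0.05), PHLDA3 (3.83 ± 0.13), PLK2 (1.23 ± 0.03) and the death receptor gene TNFRSF10B (1.14 ± 0.03) higher. Apoptosis regulators were higher in 19 and lower in 8 of 29 cases (median 0.40, camera adjusted p = 0.263), with BAK1 (1.82 ± 0.06), BAD (1.40 ± 0.05) and CFLAR (1.42 ± 0.05) higher and BCL2 (-1.60 ± 0.06) lower.

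Amino acid response genes moved both ways, more of them lower. PHGDH, the entry enzyme of serine synthesis, went from 62.1 ± 0.826 to 1.95 ± 0.271 CPM (SD, n = 3). The glycine-forming enzyme gene SHMT2 (log2 fold change -1.88 ± 0.03) and the asparagine synthetase gene ASNS (-1.79 ± 0.05) were lower and DDIT4, an mTOR inhibitor, was higher (3.59 ± 0.05). Of the 30 tested amino acid response genes 18 were lower and 11 higher, with a median of -0.26 (limma camera adjusted p = 0.0250; adjusted p = 0.243 with an estimated correlation, 0.0552 without a low-count filter and 0.113 with limma-voom). Hypoxia and glycolysis genes were higher in 24 of 33 cases and lower in 6, with a median of 0.47 (camera adjusted p = 1.19e-04; adjusted p = 0.130 with an estimated correlation). They included the glucose transporter gene SLC2A1 (2.33 ± 0.04), NDRG1 (2.21 ± 0.04) and the collagen prolyl hydroxylase gene P4HA2 (2.60 ± 0.05).

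Unfolded protein response genes were higher in 21 of 30 cases and lower in 5, with a median of 0.52 (limma camera adjusted p = 0.0156; adjusted p = 0.361 with an estimated correlation). SEC24D was higher (log2 fold change 1.67 ± 0.05) and PPP1R15A, a phosphatase subunit induced by stress, lower (-1.63 ± 0.04). Oxidative stress response genes were higher in 14 of 21 cases and lower in 7, with a median of 0.50 (camera adjusted p = 0.0156; adjusted p = 0.130 with an estimated correlation and 0.0590 with limma-voom). TXNRD1 (1.21 ± 0.03), ABCC3 (3.14 ± 0.08) and AKR1C3 (3.41 ± 0.11) were higher. In the metallothionein list the abundant members MT2A (-2.05 ± 0.04), MT1E (-1.41 ± 0.04) and MT1X (-1.42 ± 0.07) were lower. MT1A, with 0 reads in scramble, was at least 52.8-fold higher, and in all 2 of 5 were higher and 3 lower. The list's median was -1.41 and its mean 1.40, and the camera test gave a lower direction (adjusted p = 0.0421) that was lost with an estimated correlation (adjusted p = 0.373), without a low-count filter (0.514), with limma-voom (0.343) and without labelled knockdown replicate 3 (0.0523).

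Lipid and respiration lists moved both ways and did not pass limma's camera test. Cholesterol synthesis genes were higher in 14 and lower in 8 of 25 cases (median 0.24, adjusted p = 0.198), with LSS (log2 fold change 1.23 ± 0.04) and EBP (1.32 ± 0.05) higher and FDFT1 (-0.89 ± 0.04) lower. Fatty acid synthesis genes were higher in 8 and lower in 7 of 16 (median 0.08, adjusted p = 0.749), with SREBF1 (1.44 ± 0.05) and ELOVL1 (1.16 ± 0.04) higher and ACSL3 (-1.67 ± 0.04) and FADS1 (-0.72 ± 0.03) lower. Nuclear genes of oxidative phosphorylation were higher in 16 and lower in 14 of 35 (median 0.07, adjusted p = 0.233), with NDUFA4 (2.16 ± 0.06), ATP5A1 (0.88 ± 0.03) and ATP5O (1.33 ± 0.05) higher and UQCRB (-0.80 ± 0.03) lower.

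Lists of markers of other cell types were mixed. These lists held 20 leukocyte, 13 fibroblast, 12 endothelial and 13 HEK293 markers, and those not tested had too few reads to pass the low-count filter. Of 7 leukocyte markers tested, 3 were higher and 3 lower: CD14 was higher (log2 fold change 4.67 ± 0.25), and LCP1, CD68 (-0.88 ± 0.03) and LAPTM5 (-0.80 ± 0.04) were lower. That list's median was -0.0016 and its mean 0.17, while limma's camera test gave a lower direction (adjusted p = 0.0140) that was lost with an estimated correlation (adjusted p = 0.305), without a low-count filter (0.633) and with limma-voom (0.642). Fibroblast markers were higher in 5 and lower in 1 of 6 cases, with a median of 3.65, or 3.32 with genes of 0 reads in 1 group at their bound (camera adjusted p = 0.141), and COL1A2 rose from 0.0617 ± 0.0736 to 7.45 ± 0.742 CPM (SD, n = 3). PDGFRB (2.84 ± 0.14), FBLN1 (4.45 ± 0.37) and COL1A1 (1.21 ± 0.12) were higher too. Endothelial markers were higher in 4 and lower in 3 of 7 (median 0.55, mean -1.29, camera direction lower, adjusted p = 0.291), with the receptor gene TIE1 lower (-7.59 ± 0.11). ROBO4 (-0.99 ± 0.05) was also lower, and EGFL7 (1.26 ± 0.08) and ESAM (0.55 ± 0.04) were higher. Embryonic kidney (HEK293) markers were higher in 2 and lower in 5 of 7 (median -0.35, mean -0.16, camera direction higher, adjusted p = 0.978), with WT1 (7.40 ± 0.22) and PAX8 (2.98 ± 0.11) higher and SIX2 (-1.24 ± 0.08) lower. NCAM1 had 678 reads in scramble and 1 in the other group (ratio 766, 95% counting interval 137 to 30287).

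Breast lineage markers moved apart as well. Luminal markers were higher in 7 and lower in 6 of 15 cases (median 0.03, mean -0.58, camera direction higher, limma camera adjusted p = 0.517), with the pioneer factor FOXA1 falling from 21.8 ± 1.58 to 0.0532 ± 0.0240 CPM and SPDEF rising from 2.34 ± 0.472 to 61.5 ± 0.977 (SD, n = 3). XBP1 was higher (log2 fold change 1.37 ± 0.05). Basal markers were higher in 5 and lower in 2 of 8, with a median of 1.60 (camera adjusted p = 0.00453; adjusted p = 0.291 with an estimated correlation, 0.0674 without a low-count filter and 0.129 with limma-voom). They included MYLK (3.69 ± 0.06) and TRIM29 (4.13 ± 0.23).

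Genes often used as references were not stable between the groups, with 15 of 26 higher and 7 lower (median 0.39, limma camera adjusted p = 0.354). POLR2A, the largest subunit of RNA polymerase II, went from 1047 ± 50.8 to 271 ± 6.36 CPM (SD, n = 3), and RAB7A was lower (log2 fold change -0.94 ± 0.03), while YWHAZ (1.13 ± 0.03) and VCP (1.03 ± 0.03) were higher, each under all 3 other scalings too. Ribosomal protein genes were higher in 18 and lower in 18 of 46 cases (median -0.01, camera adjusted p = 0.342), with RPS4X (-1.34 ± 0.03), RPL11 (-1.31 ± 0.03), RPS24 (-1.17 ± 0.03) and RPS3 (-1.08 ± 0.03) lower and RPS18 (0.90 ± 0.03), RPS19 (0.70 ± 0.04) and RPLP0 (0.61 ± 0.03) higher. Replication-dependent histone genes were higher in 7 and lower in 1 of 11 (median 0.81, camera adjusted p = 0.697), with HIST1H1E (2.47 ± 0.31), HIST1H1C (0.48 ± 0.06) and HIST1H2AC (0.96 ± 0.15) higher and HIST1H2BK (-0.43 ± 0.05) lower. Their transcripts largely lack poly(A) tails, so these counts are a small part of the histone RNA. Ribosomal protein and metallothionein genes can have near-identical copies, and their values are uncertain for that reason. The degree differed between ribosomal protein genes. Along 1 transcript each, 98.45% of 50-base stretches in RPL11 were found in no other gene's transcripts, against 54.13% in RPLP0.

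Of the 42 lists tested, 21 passed limma's camera test with the preset correlation, 17 higher and 4 lower (leukocyte markers, amino acid response, S phase and metallothioneins). With an estimated correlation 4 held: NF-kB targets, chemokines and cytokines, matrix proteases and inhibitors, and angiogenesis factors. Counts adjusted over the list alone equalled those over all genes for each list except fatty acid synthesis, where 8 were higher and 8 lower, and histones, where 6 were higher and 1 lower. Lists past the threshold kept their direction and call under the 3 other scalings. Leaving aside the SCUBE family, TAPBPL, the genes at window ends and those named only as reported features of MDA-MB-231, the 200 genes chosen to be named all passed edgeR's quasi-likelihood test (largest adjusted p 6.36e-07, for CD274), with the 3 libraries labelled knockdown all above or all below the 3 scramble libraries. That they passed follows from their choice, by adjusted p or after their values were seen. Of all tested genes, 85.8% had no overlap between the groups.

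**Figure D3:**
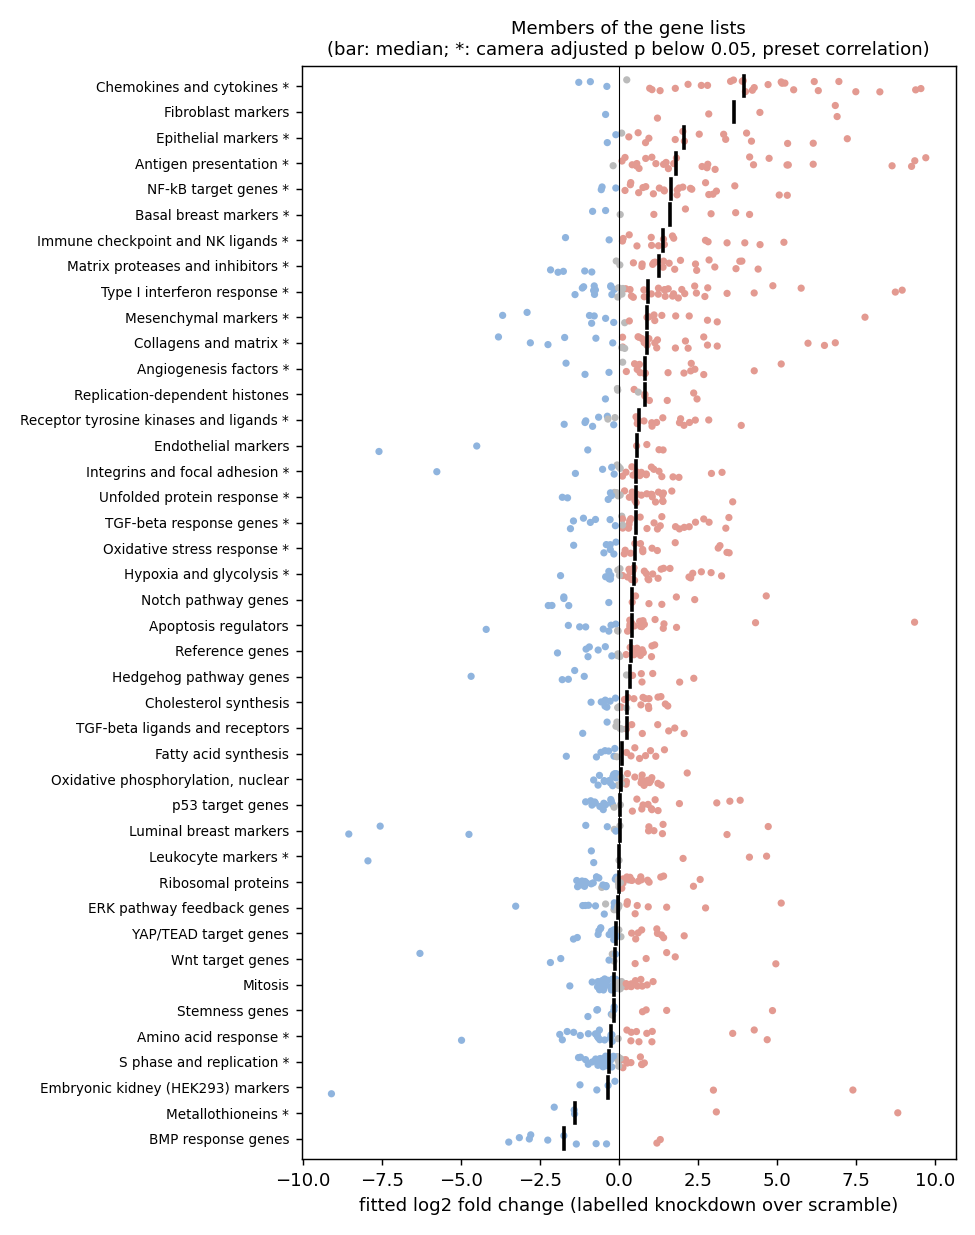
Fitted log2 fold changes, labelled knockdown over scramble (horizontal axis), of the tested members of each of 42 gene lists (1 line of points per list), red where higher and blue where lower at an adjusted p below 0.05 and grey otherwise, with each list's median as a bar and an asterisk where camera with the preset correlation passed. Chemokines and cytokines have the highest median at 3.96 and BMP response genes the lowest at -1.75, and 28 of 29 antigen presentation genes are red.

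Neighbouring genes tended to differ in the same direction, an examination added after the data were seen. When tested genes were put in chromosomal order and cut into 121 windows of 100 genes, 17 window medians lay beyond every median found in 1000 shuffles of gene order (0.55 in size), 9 higher and 8 lower in the libraries labelled knockdown. On chromosome 6, the first 4 windows, from DUSP22 to FAM83B and with the HLA genes inside, had medians of 0.84, 0.84, 0.91 and 0.67, and the last, from HEBP2 to TBP, -0.69. On chromosome 12, the first 4 windows, from KDM5A to DYRK2, had medians of -0.60, -0.83, -0.63 and -0.76. The window from SNORA31 to BIVM on chromosome 13 had -0.77. The SD of the window medians was 0.361, against at most 0.136 in the shuffles (permutation p = 0.001, the smallest that 1000 shuffles can give). Fold changes also rose with GC content across genes (Spearman's rho 0.253 over 12999 genes, which are not independent), and 14 of 117 windows lay beyond their shuffles after correction for GC content and length.

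**Figure D4:**
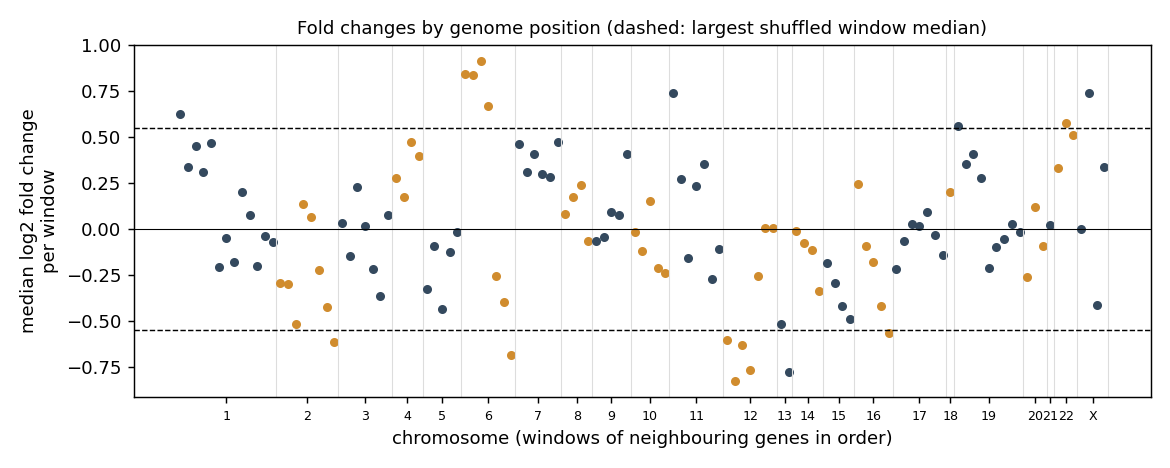
Median log2 fold change, labelled knockdown over scramble (vertical axis), in each of 121 windows of 100 neighbouring tested genes, in order along chromosomes 1 to 22 and X (horizontal axis, alternating colours). Dashed lines mark the largest shuffled window median, 0.55 in size, and the starts of chromosomes 6 and 12 lie beyond them on opposite sides.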

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

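The tests on SCUBE3 RNA, on sequencing depth, on a line that keeps the genes at 9p21, on GC content as the whole cause of the blocks of neighbouring genes, and on the splits of the libraries were chosen after their results were seen. The tests on 9p21 and on windows of genes were added after the gene-level results were seen but before their own. The bounds for the other tests of GC content and length and for shared reads were also set before those results, but the choice of transcripts behind them was changed after a first count of genes under the correction and first values of uniqueness had been seen. Reads that fell in more than 1 gene, a quantity outside the comparison, were more frequent in the files labelled knockdown, at 0.593% of the total against 0.537% in scramble, with no overlap between the groups.

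Most genes differed between the groups (11681 of 13606) while SCUBE3 did not pass. If both groups began at the same SCUBE3 level, a large drop of SCUBE3 RNA as the cause is argued against by the lower bound of its 95% interval, a log2 fold change of -0.26, and a drop of up to 16.6% is not excluded. Whether they began at the same level is not known, and the interval covers only the spread between these libraries. GC content or transcript length as the cause of most changes of at least 2-fold is argued against by the share that outlasted correction. Of 4011 genes changed at least 2-fold, 83.7% stayed past the threshold and 2-fold after it. The binomial 95% interval of that share, 82.5 to 84.8, treats genes as independent. They are not, so the interval understates the uncertainty. Changes of less than 2-fold were not put to this test. CDKN2A, CDKN2B and MTAP, neighbours at 9p21 that are reported deleted in MDA-MB-231, had at most 1 read in any library, which argues against a line that keeps them in either group. Different starting cells, such as a divergent stock, another line without these genes or a mislabelled set, cannot be told apart from an effect of the shRNA, because 0 of the 3 genes exceeded 1 CPM in every library of either group and the origin of the cells would follow the groups; a change of SCUBE3 protein alone and effects of the shRNA on other genes stay open as untested. Of the 10 splits of the 6 libraries, only the real 1 gave as many genes (11681 against 0 for the highest other, with at most 9 at an unadjusted p under 0.05, edgeR) and as many lists (21 against 14), but 10 splits are too few for a share under 0.05. Every other split also mixes both groups unevenly, so part of the difference between the groups stays in its comparison. That difference also enters the spread within each side. Few gene calls follow from that in any case, and no conclusion is drawn from the splits.

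Ribosomal protein genes, which encode parts of 1 particle, moved in both directions, 18 higher and 18 lower of 46. GC content or length as the cause of this spread is argued against by the SD of their log2 fold changes, 0.861 before and 0.843 after correction (97.9%). After correction 17 members were higher and 24 lower, so the even split did not hold but both directions remained. Over the 15 members with at least 90% of their 50-base stretches found in no other gene's transcripts, the SD was 0.853, 99.1% of that over all members. Of these 15, 4 were higher and 8 lower. Reads shared with pseudogenes and paralogs stay undecided, because uniqueness was measured along 1 transcript per gene and not where the reads fell. That transcript held 7637 stretches for RPL37 and 7023 for RPL14, against 681 for RPL27, all among the 15. Different cells in the 2 groups stay open here too, as untested.

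Some genes were read in 1 group only, and blocks of neighbouring genes shifted together. Depth as the cause of the missing genes is argued against by pairs of libraries: genes with 0 reads in the shallower and at least 10 in the deeper numbered 198 to 218 in the 9 pairs across the groups and 0 to 3 in the 6 pairs within a group, although depth differed by up to 1.14-fold within a group and 1.001-fold in the pair across groups closest in depth, which had 213. Sublines with different chromosome copy number may account for the blocks, since 17 windows of 100 genes lay beyond every shuffled order. Shared regulation of neighbours would give blocks too and was not told apart from copy number. The HLA genes alone do not account for the block on chromosome 6. Its windows from DUSP22 to HIST1H4H and from TBC1D22B to FAM83B, which hold no HLA genes, had medians of 0.84 and 0.67. GC content or length as the whole cause of the blocks is argued against by the SD of window medians after correction. It was 0.324, against at most 0.136 in shuffled orders. Whether GC content or length accounts for a part of the blocks is neither shown nor excluded. The 14 windows beyond their shuffles after correction, against 17 before, lie within the 14 to 21 found when 1 library was left out.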

How the results depend on the processing

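The correction for GC content and length, the windows and the genes without reads in 1 group were added after the data were seen; the other settings were planned. The 3000 values of 200 named genes under 15 alternatives kept their direction and their side of the threshold, which says little about stability, since these genes were chosen for large or clear changes or after their values were seen. The count of 11681 genes became 11295 with DESeq2, 11640 with limma-voom, 12483 without a low-count filter, 11065 at an adjusted p of 0.01 and 11284, among 12999 genes in place of 13606, after the GC and length correction; it was 6251 in a test against a 1.5-fold change. Its split into 5899 higher and 5782 lower became 6204 and 5460 with library totals. After the correction, which also left out genes without a known GC content or length, it was 5873 and 5411. Leaving out 1 library gave 11450 to 11630 genes, 5806 to 5878 higher and 5644 to 5752 lower, 4305 to 4389 with a log2 fold change of at least 1 in size, 20 to 21 lists, 14 to 21 windows (12 with library totals, 12 with windows of 50 genes), and 52 to 77 and 29 to 39 genes without reads in scramble and in the other group. The log2 fold change of SCUBE3, which did not pass, ranged over these from -0.0503, without scramble replicate 3, to 0.0796, and was 0.117 (adjusted p 0.433) after the GC and length correction. Of 42 lists, 4 passed with an estimated correlation and 41 with fry, which asks whether a list's genes move one way and does not compare them with other genes. The direction of lists that did not pass turned for the HEK293 markers (adjusted p 0.999 with library totals, 0.756 without a low-count filter, 0.654 with limma-voom, 0.983 with the replicate block, 0.947 and 0.939 without scramble replicates 1 and 3, within 0.915 to 0.977 over all 6 libraries left out), YAP/TEAD targets (0.940 without a filter, 0.870 with limma-voom), Hedgehog genes (0.997) and stemness genes (0.912, both with limma-voom); the cause was not tested. The replicate block gave 11706 genes, 21 lists and 0.02 for SCUBE3. The numbers do not pair the libraries: deviations of same-numbered libraries correlated at 0.0171, 0.0064 and 0.0007, and scramble 3 correlated best with another number. DESeq2 gave no list tests. At 80 to 107 reads per library, the 95% interval of SCUBE3 spans 0.834 to 1.24 times the scramble level, so a change within that span is not excluded.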

Other observations

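The genes in this part were chosen after their values were seen. Several abundant transcripts moved by large factors. NCL, which encodes the nucleolar protein nucleolin, had 4152 ± 138 CPM in scramble and 934 ± 12.02 in the libraries labelled knockdown (SD, n = 3; log2 fold change -2.15 ± 0.03, SE), and the chaperone gene HSPA8 had 5946 ± 103 and 2403 ± 37.6 (-1.31 ± 0.03). The cytoskeletal genes ACTB (0.77 ± 0.03) and FLNA (1.02 ± 0.03) were higher. SAA1, an acute-phase protein, went from 0.297 ± 0.107 to 160 ± 5.99 CPM, the surface protein MSLN from 0.0918 ± 0.0505 to 41.7 ± 1.43 and the receptor GPR110 from 0.109 ± 0.0981 to 51.8 ± 1.29. In the other direction, the collagen chaperone FKBP10 went from 159 ± 13.3 to 0.199 ± 0.140 CPM and the synaptic scaffold SHANK1 from 46.0 ± 2.50 to 0.0533 ± 0.0620.

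The cancer-testis antigen genes MAGEA6 and MAGEC1 went in opposite directions: MAGEA6 had 52.99 ± 1.44 CPM in scramble and 0.211 ± 0.112 in the libraries labelled knockdown (SD, n = 3), while MAGEC1 had 1 read in scramble and 802 in the other group. MAGE genes resemble one another, so the split of their reads is uncertain. Of genes reported as high in MDA-MB-231, AXL had 1282 ± 59.1 and 1140 ± 8.004 CPM, EGFR 394 ± 7.13 and 220 ± 17.4, and CD44 578 ± 2.26 and 1046 ± 14.2. Of genes reported as low in that line, CDH1 had 0.0458 ± 0.0478 and 2.01 ± 0.332 CPM, while GATA3, with 5.91 ± 0.134 and 15.5 ± 0.311, and ERBB3, with 12.2 ± 0.9498 and 5.86 ± 0.673, were read in both groups.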
